A study of Caenorhabditis elegans with 4 samples.

How the data were processed

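Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on third-larval-stage (L3) Caenorhabditis elegans hermaphrodites that carry NHR-11 fused to green fluorescent protein (GFP). NHR-11 belongs to the nuclear hormone receptor family of transcription factors. Per the labels, the fusion gene is a transgene introduced by particle bombardment into an unc-119(ed3) strain, and the listed genotype holds no change to the animals' own nhr-11. Per the labels' protocols, synchronized worms were grown at 20 °C on E. coli HB101, fixed with 2% formaldehyde, sonicated and precipitated with anti-GFP antibodies, and 10% of the lysate (or 50 µl) was set aside as input. The samples are 2 ChIP libraries and 2 input libraries, numbered 1 and 2 in each group. Nothing in the labels says whether the replicates came from separate cultures, so agreement between them measures only the spread between these 2 samples.

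The authors deposited 3 lists of peaks, 1 for each ChIP replicate and 1 for the whole series. Per the file headers, coordinates are on WormBase WS220, and the source column names PeakSeq as the peak caller. Each deposited peak carries a start, an end and 1 significance value, and these p-values or q-values (which of them is not stated) end just under 0.001 in each list, the lowest being the strongest; 1 series peak is listed at 0. Peaks listed by the authors with a stronger value were ranked higher within a list. How the authors made the series list, from pooled reads or otherwise, is not given in the sources used here. The aligner, the control used for each list and the threshold are not given there either. Only peaks on chromosomes I to V and X were kept here. Peak names hold a running number that follows the significance value closely (Spearman's rho of 1.00 across peaks in each list), and 24 numbers in replicate 1, 14 in replicate 2 and 169 in the series list have no peak in the lists used here. An absent number may belong to a peak left out here or be missing from the authors' list. The files hold no read counts, so the sequencing depth behind each peak is unknown. Input libraries were not analysed here. Intervals on shares of peaks are exact (Clopper-Pearson) 95% binomial intervals; they cover counting error over peaks only and treat neighbouring peaks as independent.

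Peaks of the 2 replicate lists that overlapped by at least 1 bp were merged into shared regions. The overlap was compared with 1000 random circular shifts of the replicate 2 peaks along each chromosome (one-sided permutation test; the smallest p it can give is 0.001). Agreement of the significance values was measured with Spearman's rho across shared regions, taking the strongest peak of each list in each region, with 100000 random pairings (two-sided; the smallest p is 1e-05). Each chromosome's share of shared regions was tested against its share of length with a two-sided exact binomial test and Benjamini-Hochberg adjustment over the 6 chromosomes. The length of a chromosome was taken as the highest coordinate in the 3 lists, 100.16 Mb in all, because no WS220 sequence was used. Shared regions were ranked by the sum of their ranks in the replicate lists; the rule fixed for naming was to name the first 20 and give full statistics for at most 10. For ratios of −log10 values, the 1 series peak listed at 0 was set to 1e-320, and medians were given 95% intervals from 10000 bootstrap resamples of regions. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.

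The procedures were tested on simulated lists. For the replicate overlap, with 2197 simulated peaks of the replicate 1 widths, 1.18%, 31.0% and 60.4% of peaks were found shared where 0%, 30.0% and 60.0% had been planted. Planted peaks were exact copies, so this checked the counting only. For the chromosome distribution, with 1200 simulated regions of equal width a run, 100 of 100 runs called chromosome I when its density was 1.5 times that of the others, and 3 of 100 runs made any call when no chromosome differed. Simulated regions were scattered independently, whereas 43.1% of the shared regions lay within 10000 bp of another, against 23.9% with uniform placement. The rate of false calls in the simulation therefore does not carry over to the shared regions.

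The comparisons, their tests, the naming rule and most alternatives were chosen before the data were examined. The alternatives set beforehand were a stricter overlap (50% of the shorter peak, or of both peaks), the better-scoring 50% of each list, another chance placement, peak width in place of the significance value, each replicate alone, the series list in place of the shared regions, and a value limit 10 times stricter. Leaving out peaks under 50 bp, joining regions within 10000 bp, and leaving out the stretch between 9 and 10 Mb of chromosome IV were added after the data were seen. Positions of regions relative to genes, the gene lists planned for nuclear receptors and tissues, the window around nhr-11, unc-119, and sequence motifs were not analysed here. They need a WS220 annotation or sequence, and the gene table used here is of another assembly (WBcel235), without strands; coordinates of the 2 assemblies were not mixed. Regions are therefore named by their WS220 coordinates, not by genes.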

Results

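Binding of GFP-tagged NHR-11, a nuclear hormone receptor, was mapped by ChIP-seq in L3 hermaphrodites with 2 ChIP replicates and 2 input libraries. PeakSeq peaks were listed for each ChIP replicate and for the series as a whole. The replicate 1 list held 2197 peaks on chromosomes I to V and X, with a median width of 258 bp (interquartile range 148 to 384 bp). In replicate 2, 1939 peaks had a median width of 295 bp (199 to 420 bp). Peaks covered 0.696% of the chromosome length in replicate 1 and 0.694% in replicate 2. The series list was longer, with 7089 peaks of a median width of 200 bp (97 to 339 bp), and covered 1.90%. Peaks wider than 1000 bp made up 2.32% of the replicate 1 list, 2.94% of the replicate 2 list and 2.2% of the series list. All 3 lists ended just below a significance value of 0.001. No read counts accompany the lists, so the depth of each library is unknown. Values of the input libraries were not analysed here, so no test between ChIP and input was made.

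The first comparison asked which sites were bound in both replicates. Most sites called in each replicate were called in the other, and the strongest sites were nearly always called in both. In replicate 1, 1215 of 2197 peaks (55.3%, 95% interval 53.2 to 57.4%) overlapped a replicate 2 peak. In replicate 2, 1219 of 1939 peaks (62.9%, 60.7 to 65.0%) overlapped a replicate 1 peak. Together these peaks formed 1212 shared regions with a median width of 381 bp. Random circular shifts of the replicate 2 peaks gave an overlap of 1.37% of replicate 1 peaks on average and 2.41% at most, so the observed overlap was 40.3 times the chance value (one-sided permutation test over 1000 shifts, p = 0.001, the smallest possible).

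Sharing fell with peak strength. In the strongest of 4 equal parts of the replicate 1 list, 519 of 550 peaks (94.4%, 92.1 to 96.1%) had a replicate 2 peak, against 136 of 549 (24.8%, 21.2 to 28.6%) in the weakest part. The replicate 2 list went from 473 of 485 peaks (97.5%, 95.7 to 98.7%) in its strongest part to 164 of 484 (33.9%, 29.7 to 38.3%) in its weakest. All of the first 100 peaks of each list were shared. Peaks found in 1 replicate were narrower, with a median width of 152 bp against 330 bp for shared peaks in replicate 1, and 203.5 bp against 342 bp in replicate 2. Of the 195 replicate 1 peaks under 50 bp, 11 were shared (5.64%, 2.85 to 9.87%). The strongest site called in replicate 2 alone lay on chromosome I at 5018052 to 5018745 and ranked at place 160 of that list. The strongest called in replicate 1 alone lay on chromosome X at 4137451 to 4138102 and ranked at place 238. These sites were chosen after their values were seen.

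**Figure D1:**
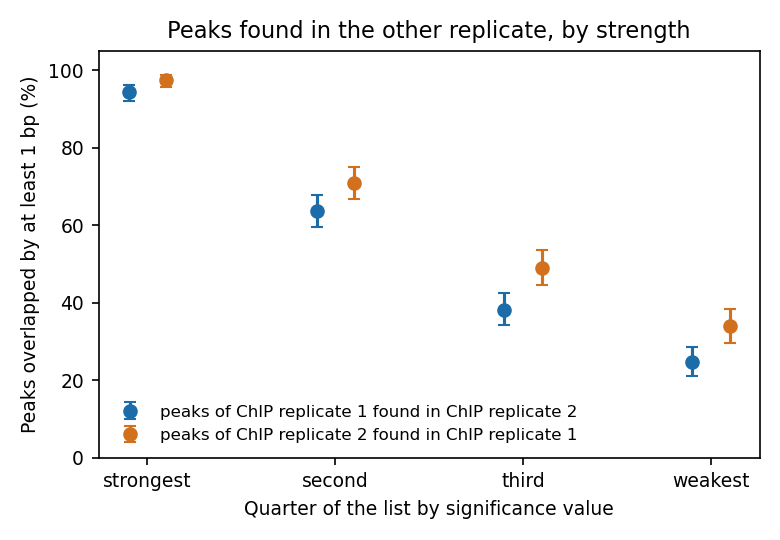
Percent of peaks in each of 4 equal parts of a replicate's list (x axis, by significance value, strongest first) that were overlapped by at least 1 bp in the other replicate (y axis). Points are shares and bars exact 95% binomial intervals; the share fell from 94.4% to 24.8% for replicate 1 peaks and from 97.5% to 33.9% for replicate 2 peaks.

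The second comparison asked which sites had the strongest significance values. The 3 first-ranked regions of chromosome IV stood out by their width and lay next to each other. The region at 9067487 to 9078958 (11472 bp) ranked first in both replicates, with values of 3.1e-130 in replicate 1 and 9.04e-81 in replicate 2. The region at 9049739 to 9057099 (7361 bp) ranked second in both, with values of 4.31e-107 and 6.23e-78. Between them, the region at 9062413 to 9066048 (3636 bp) held place 3 in replicate 1 (7.73e-76) and place 6 in replicate 2 (4.56e-56). Peaks covered 76.5% of the 29220 bp from the first start to the last end in replicate 1 and 76.8% in replicate 2. Elsewhere, the most densely covered window of that length reached 35.4% in replicate 1 and 36.1% in replicate 2, in both cases on chromosome II from position 10540601. The 6 edges of these 3 peaks differed between replicates by 1 to 7 bp, apart from the leftmost start, which differed by 105 bp. The stretch between 9 and 10 Mb that holds them had 24 series peaks, against a mean of 107 (SD 21.5) in the 16 other complete 1 Mb bins of chromosome IV. Each replicate had 13 peaks there, against means of 23.6 (SD 7.57, range 11 to 39) in replicate 1 and 18.4 (SD 6.29, range 10 to 31) in replicate 2. In the replicate lists the count of the stretch thus lay within the range of the other bins. Whether the strain carries extra copies of this stretch was not analysed here, so these ranks are those of the lists and not a measure of occupancy.

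**Figure D2:**
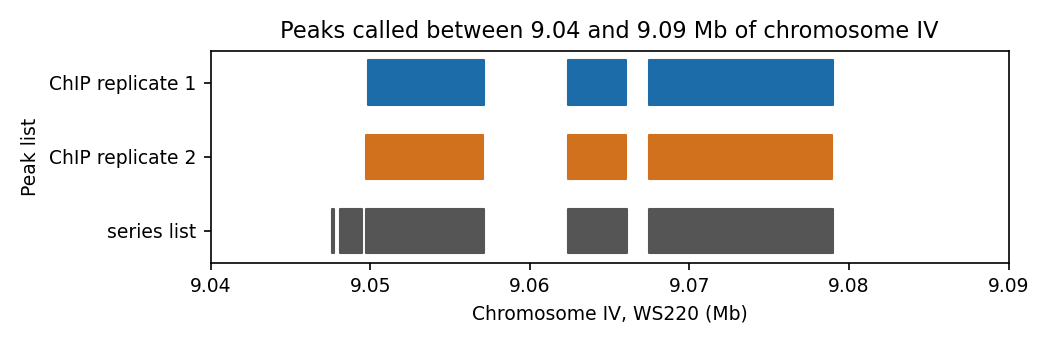
Peaks called along the stretch of chromosome IV (x axis, WS220 position in Mb) that holds the first-ranked regions, with 1 line for each peak list. Each bar spans 1 peak from start to end, and the same 3 broad peaks appear in both replicates and in the series list.

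The other regions among the first 20 were narrower. On chromosome III, the region at 4237589 to 4238156 (568 bp) had values of 1.13e-58 and 2.55e-62 in replicates 1 and 2. Chromosome X held the region at 8035950 to 8036914 (965 bp; 8.23e-65 and 6.66e-61) and the region at 14525364 to 14526319 (956 bp; 2.71e-56 and 1.98e-56). Further X regions, at 6296010 to 6296896 and at 2996419 to 2997463, ranked at places 7 and 7 and at places 9 and 8 of the replicate lists. The region on chromosome III at 3866895 to 3867768 and that on chromosome X at 16056101 to 16056808 completed the first 10. Places 11 to 20 by summed rank were taken by chromosome II at 10563003 to 10563860, chromosome III at 4281627 to 4282667 and at 10758944 to 10759377, and chromosome I at 7079195 to 7081367 and at 9380938 to 9382029. Chromosome X added 5 regions there, starting at 11093799, 13700459, 9465436, 12362612 and 16929358. The first 20 regions had widths of 434 to 11472 bp with a median of 960.5 bp, and 10 of them lay on chromosome X, 4 on III, 3 on IV, 2 on I, 1 on II and 0 on V.

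Strength in 1 replicate followed strength in the other. Across the 1212 shared regions, Spearman's rho between the significance values of the replicates was 0.719 (permutation test over 100000 pairings, p = 1e-05, the smallest possible). Genomic regions are not independent replicates, so rho describes these 2 lists. Of the first 10 peaks of replicate 1, 9 overlapped one of the first 10 of replicate 2, and 78 of the first 100 overlapped one of the first 100. Widths followed each other as well, with a rho of 0.837.

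**Figure D3:**
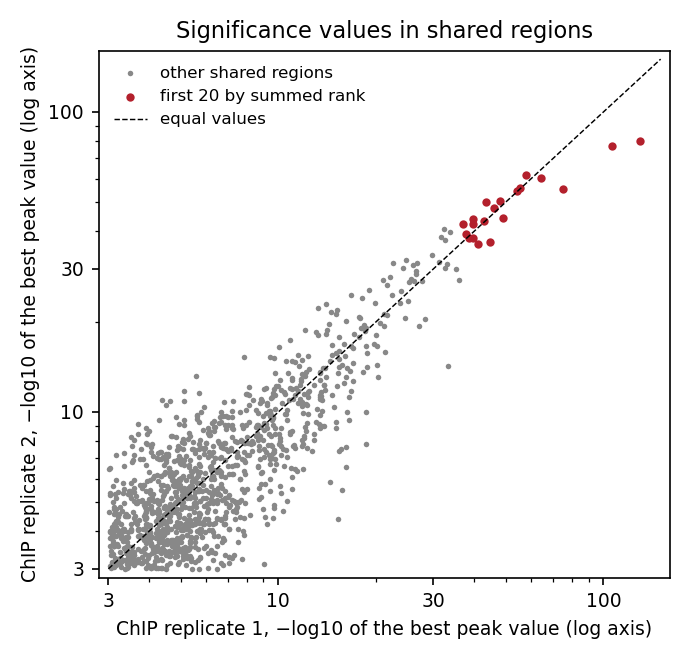
The −log10 significance value of the strongest peak in each of the 1212 shared regions, in replicate 1 (x axis) and replicate 2 (y axis), both on log axes. Red points are the first 20 regions by summed rank and the dashed line marks equal values; the points rise together with a Spearman's rho of 0.719.

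The third comparison set the series list beside the replicate lists. Nearly every replicate peak was in the series list, which held many further, narrower peaks. Of the replicate 1 peaks, 2052 (93.4%, 92.3 to 94.4%) overlapped a series peak, as did 1845 of the replicate 2 peaks (95.2%, 94.1 to 96.1%) and all 1212 shared regions. In the other direction, 2618 of 7089 series peaks (36.9%, 35.8 to 38.1%) overlapped a peak of at least 1 replicate, 1223 (17.3%, 16.4 to 18.2%) overlapped both, and 4471 (63.1%, 61.9 to 64.2%) overlapped neither. Among the better-scoring 50% of the series list, 65.1% of peaks overlapped a replicate peak. All of the first 100 series peaks overlapped both replicates. Series peaks found in neither replicate had a median width of 146 bp and a median value of 4.19e-05, against 328 bp and 4.01e-10 for the rest. They made up 74.3% (72.2 to 76.4%) of the series peaks on chromosome IV and 65.5% (63.3 to 67.6%) on chromosome I, and between 51.3% and 60.9% on chromosomes II, III, V and X. Of peaks called in 1 replicate alone, most were in the series list: 837 of the 982 peaks called in replicate 1 alone and 626 of the 720 called in replicate 2 alone overlapped a series peak. The series has only these 2 ChIP libraries, so its list is not independent of the replicate lists. Overlap with a series peak therefore lends no separate support to a site.

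The last comparison asked how binding was spread over the chromosomes. Chromosome I carried more shared regions than its share of the length and chromosome V fewer. Chromosome I held 302 of the 1212 regions (24.9%, 22.5 to 27.5%) on 15% of the length, a density ratio of 1.66 (1.5 to 1.82) that passed the exact binomial test (adjusted p = 1.99e-18). Chromosome V held 154 regions (12.7%, 10.9 to 14.7%) on 20.9% of the length, a ratio of 0.609 (0.521 to 0.705; exact binomial test, adjusted p = 4.58e-13). The other chromosomes did not pass the test. Their density ratios were 0.923 (0.797 to 1.06) for II, 1.09 (0.949 to 1.25) for III, 0.926 (0.810 to 1.05) for IV and 0.972 (0.854 to 1.10) for X. Per Mb, chromosome I held 20.0 shared regions, III 13.2, X 11.8, II 11.2, IV 11.2 and V 7.36. Joining neighbouring regions within 10000 bp left ratios of 1.47 for chromosome I (adjusted p = 1.14e-07, exact binomial test) and 0.655 for V. The binomial test treats regions as placed independently, but 43.1% of them lay within 10000 bp of another. Its p-values are therefore too small and the intervals too narrow. Joining does not remove wider clustering: in replicate 1, complete 1 Mb bins held 25 to 63 peaks on I and 3 to 36 on V.

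The series list gave another distribution from the shared regions on chromosome IV. Its 1777 peaks there gave a density ratio of 1.44 (1.38 to 1.49), while IV had a ratio of 1.03 (0.94 to 1.13) in the replicate 1 list and 0.92 (0.82 to 1.01) in the replicate 2 list. Chromosome I stood at 1.76 (1.69 to 1.83) in the series list, 1.71 (1.59 to 1.83) in replicate 1 and 1.56 (1.44 to 1.69) in replicate 2. The series ratios of II (0.778), III (0.763) and X (0.731) lay below 1. Among the 1939 strongest series peaks, as many as the shorter replicate list holds, 25.8% (23.9 to 27.8%) lay on IV, against 18% of replicate 1 peaks and 16% of replicate 2 peaks. Chromosome I held 32.1% of them, against 25.7% in replicate 1 and 23.5% in replicate 2.

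**Figure D4:**
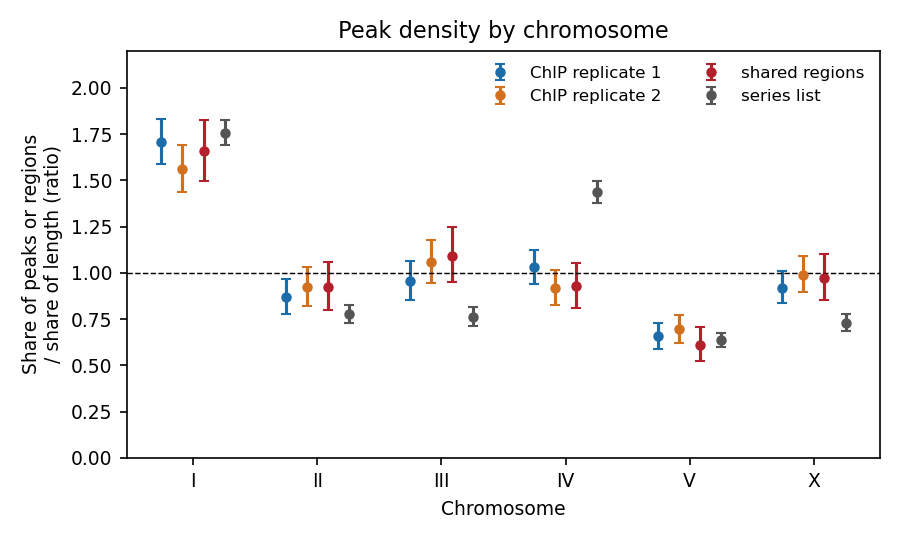
Density ratio (y axis, the share of peaks or regions on a chromosome divided by its share of the length) for each chromosome (x axis) in the replicate lists, the shared regions and the series list. Bars are exact 95% binomial intervals and the dashed line marks a ratio of 1; chromosome I lies above 1 and V below it in all 4 sets, while IV lies above it at 1.44 in the series list.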

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

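The overlap of the replicates stayed far above chance and rho stayed positive under every alternative run, and chromosomes I and V kept their calls in all 7 other region sets. The narrowest cut by rank among these sets was the better-ranked 50% of the shared regions. Of 62 alternative values, 50 kept their direction and side of the threshold or stayed within the set limits. The 12 others follow. Using the better-scoring 50% of each list left 679 shared regions instead of 1212, as fewer peaks entered. In the better-scoring 50% of the series list, 65.1% of peaks overlapped a replicate peak instead of 36.9%. A value limit 10 times stricter left 1358 peaks in replicate 1 and 1215 in replicate 2. Without replicate 2, chromosome II fell below its length share, with a ratio of 0.868 (exact binomial test, adjusted p = 0.0178), against 0.923 without replicate 1. Leaving out a replicate also took III (0.956 to 1.06) and IV (0.916 to 1.03) across 1, and joining regions within 10000 bp took X to 1.02, none of them passing the test in any of these settings. With the series list in place of the shared regions, chromosome IV went from 0.926 to 1.44 and III from 1.09 to 0.763, both crossing 1, while II (0.778) and X (0.731) became called. Shares sum to 100%, so higher shares on I and IV lower the ratios of the other chromosomes by construction. The values of II, III and X do not by themselves show a change there. Explanations for IV were tested after the excess there was seen. For the ratio of values by chromosome, the outcome looked for was written before its own result was seen. Position relative to genes, gene lists, the nhr-11 window and sequence motifs were not run, nor were their alternatives, because no WS220 annotation or sequence was used here. Leaving out short peaks, joining neighbouring regions and leaving out 9 to 10 Mb of chromosome IV were chosen after seeing the data. No paired analysis was possible because the input libraries have no list here and no test compared groups of samples. Depth is unknown, so a site called in 1 replicate may have been missed in the other. In the replicate 1 list, 24.8% of peaks in the weakest of 4 equal parts were shared, against 94.4% in the strongest. Keeping the better-scoring 50% of each list raised the shared percent of replicate 1 peaks from 55.3% to 61.9%. That setting also cut the replicate 2 list, so peaks whose match lay in its weaker 50% counted as not shared.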

Other observations

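All tests in this part were chosen after the result was seen, except that of the ratio of series to replicate values by chromosome. For that ratio the outcome looked for was written before its own result was seen. It was nevertheless chosen to explain the series-list excess on I and IV, which was already known.

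The first 20 and first 50 shared regions lay more often on chromosome X than the remaining ones, although the share of all regions on X did not pass the test against its length. Of the first 20 shared regions, 10 lay on X (50%, exact 95% interval 27.2 to 72.8%), against 16.6% of the remaining regions (Fisher's exact test, two-sided, adjusted over 6 chromosomes p = 0.00407). Among the first 50 the share was 34% against 16.4% (Fisher's exact test, adjusted p = 0.0194), and among the first 100 it was 27% against 16.3% (adjusted p = 0.0715). Among the first 303 regions, 20.5% lay on X against 16.1% (Fisher's exact test, adjusted p = 0.283). The make-up of the first 20 prompted these tests, and the larger sets include those 20. No adjustment was made over the cut-offs, so the p-values are too small. Shared regions on X had a median width of 482 bp, against 353.5 to 374.5 bp on the autosomes, while their median −log10 value (mean of both replicates) was 5.62, against 5.47 to 5.72 on the autosomes.

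Shared regions were gathered towards the middle of the chromosomes and close to one another. The middle of 3 equal parts of each chromosome together held 520 of 1212 regions (42.9%, 40.1 to 45.7%), where even spacing gives 33.3% (two-sided permutation test over 10000 circular shifts, p = 0.001). By chromosome the share ran from 31.7% on X to 52.9% on II, and no single chromosome passed the test after adjustment (adjusted p from 0.359 to 0.695). A neighbouring shared region lay within 2000 bp for 232 regions (19.1%), against 6.33% on average and 10.1% at most with uniform placement (permutation test over 1000 placements, p = 0.001, the smallest possible). The groups with the most regions, joined at 10000 bp, held 7 regions each, on chromosome IV at 14606435 to 14624262 and on II at 5326124 to 5346623. A group on chromosome X at 12200351 to 12210971 held 6.

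The series list had an excess of peaks on chromosomes I and IV, which the replicate lists also showed on I but not on IV. A few local clusters do not account for it. Of the 1 Mb bins of I and IV, 96.9% (31 of 32) held more series peaks than the median bin of the other chromosomes. Whether more sites on IV, seen alike in each replicate, account for the excess there was not tested apart from the excess itself. There lay 25.1% of all series peaks (24.1 to 26.1%), above the intervals of replicate 1 (16.4 to 19.7%) and replicate 2 (14.4 to 17.7%). Those are the counts that showed the excess on IV, so this comparison restates it and is no separate test. On I more such sites stay open: 26.4% of all series peaks (25.4 to 27.5%) lay there, within the interval of replicate 1 (23.9 to 27.6%) and above that of replicate 2 (21.6 to 25.4%), but 32.1% (30 to 34.2%) of the 1939 strongest, above both. A chromosome-wide difference in how ChIP was weighed against its control is a candidate explanation: in regions found in all 3 lists, the median ratio of series to replicate −log10 values exceeded that of the other chromosomes by 0.837 (0.780 to 0.907) on I and 1.09 (0.995 to 1.16) on IV. Values of different lists share no scale, so only the difference between chromosomes was read. The series list ends just under a value of 0.001, so raised values and more peaks on I and IV may be 1 observation. The ratio does not set weighing against the control apart from other causes of stronger series values there. Its intervals come from regions of 1 series list. Which step would have raised the values stays open, since neither control reads nor the making of the series list were analysed here. Whether the same step raised the counts on I in the replicate lists was not tested. No biological explanation beyond the number of sites was examined.

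The 3 broad peaks on chromosome IV at 9049739 to 9078958 may mark extra copies of this stretch carried by the transgene, since nhr-11 itself lies on chromosome IV. Peaks covered at least 76.5% of the stretch in each replicate, against at most 36.1% in any other window of that length; in the series list the values were 77.2% and 61.2%. The stretch was bounded by these peaks themselves, so its cover could not have argued against extra copies, and broad binding would give the same picture. Input reads, copy number and the WS220 position of nhr-11 were not analysed here, so the explanations cannot be told apart.

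The same stretch lies in a sparse part of chromosome IV: between 9 and 10 Mb the series list held 24 peaks, 22.4% (14.3 to 33.3%) of the mean of the other 16 complete 1 Mb bins (107, SD 21.5), while replicates 1 and 2 each held 13, which is 55.2% (29.4 to 94.3%) and 70.5% (37.5 to 121%) of theirs. A higher calling threshold is not the whole cause in the series list, because 65.0% of series peaks on the rest of IV were at least as strong as the weakest peak of the stretch (2.66e-05), well above the 22.4% found. It is a candidate explanation for part of the gap, since 0 of 10000 random draws of 24 series peaks from the rest of IV were as strong throughout. In the replicate lists, with 13 peaks each, the same draws decided nothing (61.3% for replicate 1 and 7.83% for replicate 2), so a higher threshold there stays open. Fewer sites in this stretch, seen alike in each replicate, also stays open. The series interval overlaps that of replicate 1 and not that of replicate 2, but these intervals leave out the spread between bins and are too narrow.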
